A study of Homo sapiens with 3 samples.

How the data were processed

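The series holds 3 RNA-seq libraries of SH-SY5Y, a human neuroblastoma cell line, as 1 group with replicates 1, 2 and 3. Per the labels' protocols, total RNA was taken from separate flasks at about 60% confluency, and stranded mRNA libraries were made from 500 ng of it. The submitters' processing notes name bcl2fastq, FastQC 0.10.1, TopHat2 2.1.1, Cufflinks 2.2.1 and the human assembly hg38. The role and settings of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. The table deposited by the authors holds 60660 genes by Ensembl identifier, with 1 FPKM value per gene and library; FPKM divides fragments by transcript length and by the library's mapped fragments. No normalization between libraries beyond that is given in the sources used here. The values summed to 1389791, 1457403 and 1375659 FPKM in replicates 1, 2 and 3.

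Identifiers were matched to GENCODE release 29 on GRCh38, the assembly also called hg38, for gene names, types, exonic lengths and coordinates; 57046 matched and 3614 did not and kept their identifiers. A name shared by more than 1 identifier (154 names) took the one with the highest mean, which left 59152 names. In 28 genes a value is missing in 1 or 2 libraries; these were left missing, and a gene needed a value in at least 2 libraries to be tested. An FPKM of exactly 0 is described as listed at 0, since it can be a failed estimate as well as a lack of reads.

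FPKM values are not counts, so no count model was used. Genes with a value above 0 in at least 1 library were tested on log2(FPKM + 0.1) against the same transform of 1 FPKM, with limma 3.58.1 in R 4.3.3 (intercept only, moderated, two-sided, Benjamini-Hochberg adjusted p under 0.05). A difference on this scale understates the distance of low genes from the level. Tested on simulated data with the spread of 31719 genes of this fit, the test placed 54% of 100 genes lying 0.5 log2 from the level on the right side and 81% of 100 genes lying 1 log2 away, and called 7% of 200 genes lying exactly at the level. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

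There were 34 gene lists with 486 genes, which covered growth factor receptors and ligands, neuroblastoma genes, lineage and transmitter genes, neuronal and glial genes, proliferation, apoptosis, angiogenesis, signalling and developmental pathways, antigen presentation, stress, hypoxia, housekeeping genes, and markers of immune, endothelial, fibroblast, epithelial, and muscle or erythroid cells. For each list the members called above, below or neither were counted, over all genes tested and over the list alone. Its median was placed among 10000 random lists of the same size from 19682 protein-coding genes, as a description with no p-value. For 25 gene pairs the log2 difference within each library was taken, with an exact two-sided sign-flip test over libraries, whose smallest p is 0.25. For 13 list pairs the log2 difference of medians, shared members left out, was tested with 100000 two-sided permutations of list membership across genes and Benjamini-Hochberg adjustment over the 13. The differences printed are those of the medians over the libraries' mean levels, and their SD is over the per-library differences.

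The genes to be named were fixed by rule: the genes of the pairs; the 3 highest members and the lowest member of each list, and every member of the neurotrophin receptor, neurotrophin, GDNF family and sympathoadrenal lists; the 20 genes with the highest mean; and the 10 with the largest SD of log2 values among genes with a mean of at least 10 FPKM. Members outside the rule that are named because they make up a count of 5 or fewer, genes on the other strand, and genes said to be so were chosen after their values were seen. Some genes that the rule names, 1 of the lists and some of the pairs are not reported here. The groups, lists, pairs, tests, naming rule and alternatives were chosen before the data were examined. The alternatives were pseudocounts of 1 and 0.01, a median-ratio rescaling, rescaling to TPM, each library left out, summed values for shared names, levels of 0.5 and 5 FPKM, a count without a test, other filters on low values, means in place of medians, another background for the random lists, and other limits for the spread between libraries.

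Depth was estimated from the table. In genes with 1 annotated transcript of at least 600 exonic bases, FPKM times effective length (exonic length less an assumed 200 bases) moved in even steps, and 97.5%, 97.4% and 97.7% of 2316, 2093 and 1759 low values lay within 0.1 of a whole number of reads, where chance gives 20%. The steps correspond to about 21500000, 28500000 and 43400000 single reads of 50 bases in replicates 1, 2 and 3, a read length taken from the labels. These are estimates, since the effective length rests on the assumed fragment length. Counting error alone was covered by the floors derived from them. The estimated depths also gave the number of reads against which mitochondrial tRNA genes were set. Recovered reads served to compare depth, to check whether any pair of libraries agreed within sampling noise and to thin replicates 2 and 3 to the depth of replicate 1 (100 draws). Because strand handling is unknown, overlap was checked: 250 list genes share their locus with an annotated gene on the other strand, and 51 of them, with a value above 0, lie at or below that gene's mean FPKM.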

Results

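RNA of SH-SY5Y cells was sequenced as 3 stranded mRNA libraries, each made from a separate culture flask. SH-SY5Y is an established human cell line from a neuroblastoma, a childhood tumour of the sympathetic nervous system that arises from the neural crest. The labels name 1 group, no treatment and no second cell line, and the series title places the data beside a logic model of developmental signals. The comparisons the design allows are therefore between genes within the same libraries: which receptors, ligands, lineage regulators and pathway genes lay above or below a fixed level, and which gene of a pair was higher. The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), and a level of 1 FPKM was used. Errors are SDs over the 3 libraries (n = 3), and calls are from limma's moderated test with Benjamini-Hochberg adjusted p.

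The reads behind the values were estimated from the steps of low FPKM values in genes with 1 annotated transcript, at about 21500000 in replicate 1, 28500000 in replicate 2 and 43400000 in replicate 3. At these depths 3 reads on a transcript with an effective length of 1 kb correspond to 0.139, 0.105 and 0.0691 FPKM, a floor that covers counting error only. The floor is lower on longer transcripts. A gene listed at 0 can be a failed estimate as well as a lack of reads. Of 31736 genes with a value above 0 in at least 1 library, 14446 were called above 1 FPKM, 13853 below, and 3437 neither. Among protein-coding genes, 11828 of 16750 tested (70.6%) were called above and 4113 below, while 449 of 3348 tested lincRNA genes were called above. The number of genes called below depends on the filter, since 5918 were called at a mean FPKM of at least 0.1 and 40037 with no filter.

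The highest values of the table belonged to mitochondrial genes and genes of the translation machinery. The mitochondrial tRNA genes MT-TC (171989 ± 25868 FPKM), MT-TS1 (137348 ± 24329), MT-TY (104252 ± 21067) and MT-TN (88336 ± 7956) were the highest, and together they held 34.4%, 38.1% and 34.4% of summed FPKM in replicates 1, 2 and 3. They have 66 to 73 exonic bases, and their FPKM is set against an effective length shorter still. Among the others of the 20 highest were MT-ATP8, MT-TE, MT-RNR2, MT-CO2, MT-ND4L, MT-ND4, MT-TI, MT-TS2, RPL23 (6151 ± 444), RPL37A, RPS27 and EEF2 (4658 ± 313), with 3 genes whose identifiers had no match in the annotation used. Housekeeping genes were all called above 1 FPKM (15 of 15), with a median of 315.0 FPKM. Among them EEF1A1 reached 4035 ± 195 FPKM, RPLP0 2790.3 ± 137 and ACTB 2577 ± 273, and the lowest was the TATA-binding protein gene TBP at 19.4 ± 0.953.

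The neurotrophin receptors, which bind survival factors of sympathetic neurons, were present at low to moderate levels. NGFR, the low-affinity receptor p75, reached 7.69 ± 0.987 FPKM and the sorting receptor SORT1 18.4 ± 2.402, both called above. NTRK2, the receptor for brain-derived neurotrophic factor (chromosome 9, 84668551 to 85027070), at 1.15 ± 0.193 FPKM (limma adjusted p = 0.251) and the neurotrophin-3 receptor gene NTRK3 at 1.09 ± 0.293 (limma adjusted p = 0.678) were called neither above nor below. Of their ligands, BDNF (0.114 ± 0.0197 FPKM) and NTF4 (0.066 ± 0.0572) were called below, and NTF3 was listed at 0. So 3 of 5 receptors and 0 of 4 neurotrophins were called above by limma, with 0 neurotrophins above at an unadjusted p under 0.05 as well. The median of the receptors stood at percentile 51.2 among 10000 random lists of protein-coding genes of the same size, and that of the ligands at percentile 7.97.

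Within libraries, the difference between NTRK3 and NTRK2 (-0.10 ± 0.38) was smaller than its spread, and its sign turned to 0.12 without replicate 3. The exact sign-flip test over 3 libraries, two-sided, cannot fall below 0.25, and 24 of the 25 gene pairs compared had 1 sign in every library and exact p = 0.25 (0.260 after Benjamini-Hochberg adjustment), so none of the pair differences passed the threshold. NTRK3 against NTRK2 gave exact p = 1. The receptors as a list exceeded the neurotrophins by 4.95 ± 0.18 (log2 difference of medians), in 3 of 3 libraries, with a permutation p across genes of 0.0468 and 0.0608 after adjustment over 13 list pairs, which did not pass the threshold. The adjusted permutation p was 0.0307 with a pseudocount of 0.01, 0.00969 with means over members and 0.0307 without replicate 2, and it was 0.0608 in the other 6 alternatives, among them those without replicate 1 and without replicate 3. BDNF shares its locus with BDNF-AS on the other strand (1.25 ± 0.375 FPKM). The values of such overlapping genes are uncertain, since the strand setting of the counting is not given in the sources used here. This holds too for TGFB1, CHRNB2, PIK3CD and FGF2, whose partners on the other strand, HNRNPUL1 (212 ± 9.77 FPKM), AL592078.1 (37.5 ± 2.81), CLSTN1 (47.6 ± 1.15) and NUDT6 (16.8 ± 0.887), were higher.

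**Figure D1:**
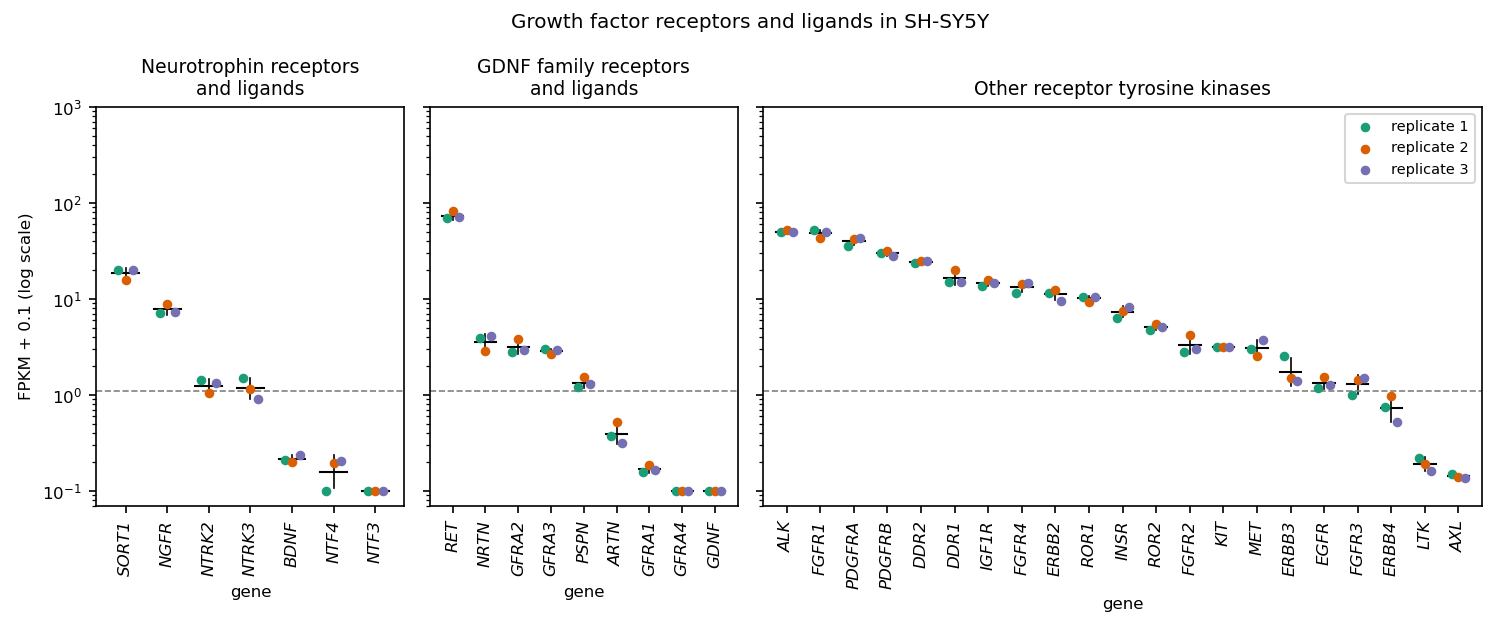
FPKM + 0.1 on a log axis for neurotrophin receptor and ligand, GDNF family and other receptor tyrosine kinase genes, with 1 point per library. The horizontal bar is at the mean of log2(FPKM + 0.1) and the vertical bar is 1 SD of these log2 values (n = 3). The dashed line marks 1 FPKM, and the FPKM values named here are arithmetic means. RET at 73.8 FPKM and ALK at 50.2 stand highest in their panels, NTRK2 and NTRK3 lie near the line, and GDNF, GFRA4 and NTF3 lie at 0.

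RET, the signalling receptor of the GDNF family ligands, was the highest member of its list at 73.8 ± 7.12 FPKM (limma adjusted p = 2.99e-05), while its ligand GDNF was listed at 0 in all 3 libraries. NRTN, which encodes the ligand neurturin (3.504 ± 0.641 FPKM), and the co-receptor genes GFRA2 (3.101 ± 0.542) and GFRA3 (2.76 ± 0.157) were called above 1 FPKM. The GDNF co-receptor gene GFRA1 (0.0693 ± 0.0157) and the ligand gene ARTN (0.302 ± 0.106) were called below, PSPN (1.24 ± 0.183) was called neither, and GFRA4 was listed at 0. In all, 4 of 9 members were called above and 2 below, and the median stood at percentile 25.6. At a level of 5 FPKM, RET alone of the 9 was called above. PSPN overlaps ALKBH7 on the other strand, which stood at 25.3 ± 3.42 FPKM.

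Among 21 other receptor tyrosine kinases, 15 were called above 1 FPKM and 2 below, with a median of 7.26 FPKM (percentile 64.3). ALK, a receptor kinase gene often mutated in neuroblastoma (chromosome 2, 29192774 to 29921566), was highest at 50.2 ± 1.22 FPKM (log2 over the level 5.51, SE 0.0664, limma adjusted p = 2.99e-05). The fibroblast growth factor receptor gene FGFR1 (48.2 ± 4.42 FPKM) and the platelet-derived growth factor receptor gene PDGFRA (40.2 ± 3.95) followed. AXL (0.0413 ± 0.0085) and LTK (0.0913 ± 0.031) were called below, and ERBB3 (1.704), EGFR (1.22), FGFR3 (1.21) and ERBB4 (0.645) were called neither. ALK lay below RET within libraries by a log2 difference of -0.55 ± 0.10, in 3 of 3.

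All 20 neuroblastoma-associated genes, a list of genes linked to the risk or course of the disease, were called above 1 FPKM (median 30.7 FPKM, percentile 99.9). ODC1 (144 ± 4.63 FPKM), which encodes the rate-limiting enzyme of polyamine synthesis, and CAMTA1 (129.9 ± 10.4) were among the 3 highest, and CD44 (2.93 ± 0.603) was lowest. MYC (chromosome 8, 127735434 to 127741434) stood at 54.6 ± 0.99 FPKM, and MYCN, the paralog amplified in aggressive neuroblastoma (chromosome 2, 15940564 to 15947007), at 6.96 ± 0.0934. Both were called above 1 FPKM, with limma adjusted p = 2.99e-05 for MYC and 5.66e-05 for MYCN. MYC exceeded MYCN by 2.95 ± 0.04 on the log2 scale in 3 of 3 libraries, a ratio of means of 7.85.

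Transcription factors of the sympathoadrenal lineage, the neural crest branch that forms sympathetic neurons and chromaffin cells, were among the most abundant lists. HAND2 (chromosome 4, 173524969 to 173530229) reached 454 ± 9.18 FPKM, PHOX2A 381 ± 10.4, GATA2 335 ± 16.1 and GATA3 286 ± 16.1. TFAP2B (134 ± 0.88 FPKM), ISL1 (103 ± 2.499), SOX4 (90.95 ± 2.54), SOX11 (41.6 ± 1.43), HAND1 (26.9 ± 2.63), TBX2 (26.3 ± 3.75), EYA1 (4.69 ± 0.8) and DACH1 (1.81 ± 0.00321) were also called above 1 FPKM. INSM1, a regulator of neuroendocrine differentiation, was called below at 0.00733 ± 0.00666 FPKM. With 14 of 15 members above, the list's median of 91.0 FPKM exceeded those of all random lists drawn (percentile 100). HAND2 exceeded HAND1 by 4.08 ± 0.17 on the log2 scale, while GATA3 lay below GATA2 by a log2 difference of -0.23 ± 0.12, each in 3 of 3 libraries. HAND2 overlaps HAND2-AS1 on the other strand, which stood at 427 ± 9.34 FPKM, and TBX2 overlaps TBX2-AS1 at 32.1 ± 4.87, so the values of HAND2 and TBX2, and the difference between HAND2 and HAND1, are uncertain.

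Genes that mark the mesenchymal type of neuroblastoma cell were lower and mixed, with 11 of 20 called above 1 FPKM and 5 below (median 1.45 FPKM, percentile 17.5). TWIST1, a transcription factor of mesenchyme and neural crest, stood at 219.8 ± 17.8 FPKM, the intermediate filament gene VIM at 23.3 ± 1.68 and TEAD4 at 13.7 ± 0.7. WWTR1 (0.548), SIX4 (0.406), ITGA5 (0.242), RUNX1 (0.133) and YAP1 (0.035) were called below, COL3A1 (0.919 ± 0.675) was called neither, and PRRX1 and MEOX2 were listed at 0. The sympathoadrenal list exceeded the mesenchymal list by a log2 difference of medians of 5.89 ± 0.07 in 3 of 3 libraries (permutation p = 0.00011, adjusted 0.000338). At a level of 5 FPKM, 5 mesenchymal-type genes were called above.

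Neural crest transcription factors gave 10 of 19 called above 1 FPKM and 6 below, with a median of 3.78 FPKM (percentile 36.4). The highest were TWIST1 and TFAP2B, which the lists above also hold, and ID2, an inhibitor of basic helix-loop-helix factors, at 91.3 ± 6.37 FPKM. PAX3 and FOXD3, regulators of early crest, were listed at 0, and SOX5 (1.27 ± 0.306 FPKM) was called neither. With TFAP2B left out of both lists, the sympathoadrenal factors exceeded the neural crest factors by a log2 difference of 4.75 ± 0.14 in 3 of 3 libraries (permutation p = 0.0118, adjusted 0.0170).

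**Figure D2:**
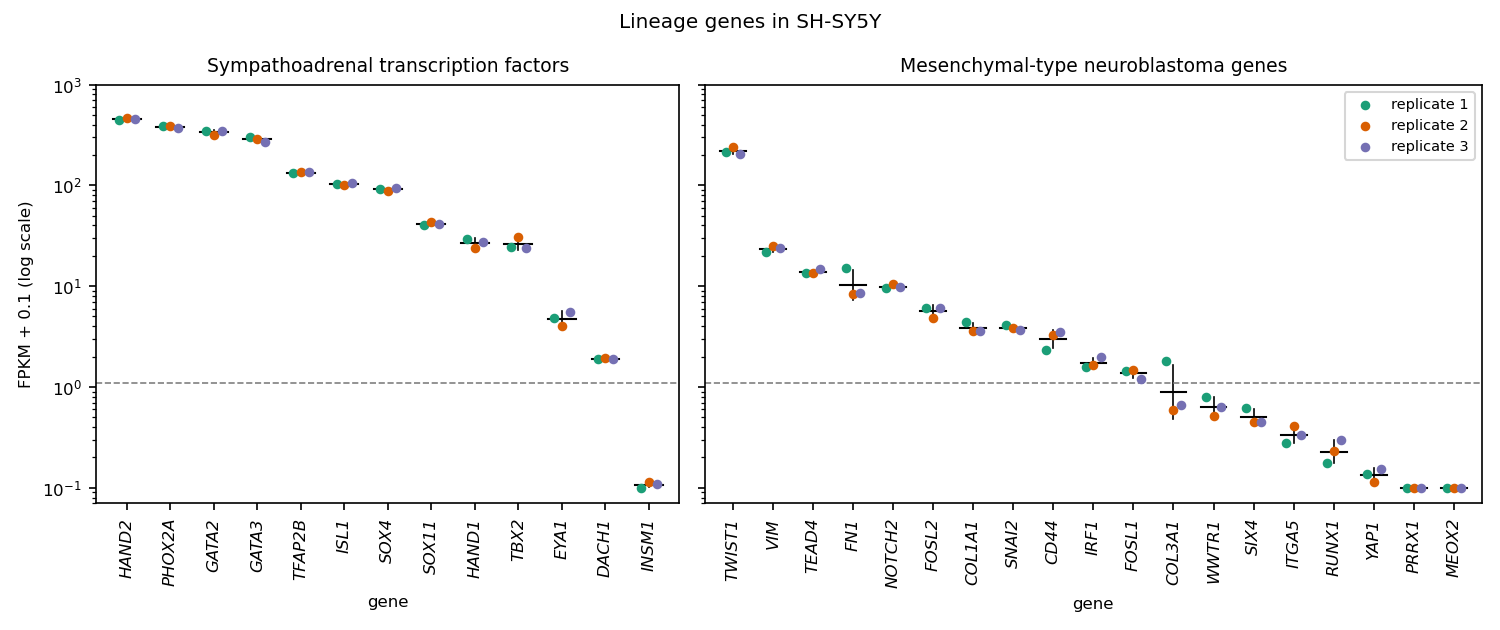
FPKM + 0.1 on a log axis for sympathoadrenal transcription factors and mesenchymal-type genes, with 1 point per library. The horizontal bar is at the mean of log2(FPKM + 0.1) and the vertical bar is 1 SD of these log2 values (n = 3). The dashed line marks 1 FPKM, and the FPKM values named here are arithmetic means. In the first panel the genes shown lie above the line, from DACH1 at 1.81 to HAND2 at 454 FPKM, except INSM1, and in the second TWIST1 at 219.8 is highest.

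Genes of catecholamine synthesis, storage and turnover were mostly expressed, with 15 of 18 called above 1 FPKM and 1 below (median 28.1 FPKM, percentile 99.7). The granule protein gene CHGA reached 376 ± 13.95 FPKM, DBH, which encodes the enzyme that makes noradrenaline, 323 ± 10.3, and CHGB 62.9 ± 1.16. TH, the gene of the rate-limiting enzyme of catecholamine synthesis (chromosome 11, 2163929 to 2171877), stood at 1.12 ± 0.0686 FPKM and was called neither above nor below (limma adjusted p = 0.148). Rescaling to TPM lowers every gene of a library alike, by a log2 shift of -0.47, -0.54 and -0.46 in replicates 1, 2 and 3 before the pseudocount, and so acts as a higher level; TH was then called below (log2 -0.30, limma adjusted p = 0.0275). PNMT, whose enzyme makes adrenaline, was called above at 1.99 ± 0.425 FPKM but not in TPM (limma adjusted p = 0.0556). The summed FPKM that sets the TPM shift includes the short genes MT-TC, MT-TS1, MT-TY and MT-TN. They held 34.4%, 38.1% and 34.4% of it in replicates 1, 2 and 3, so calls in TPM depend on their values. A rescaling without them was not run. The vesicular transporter gene SLC18A1 stood at 7.27 ± 0.168 FPKM and SLC18A2 was called below at 0.186 ± 0.0344, beside PDZD8 on the other strand at 22.00 ± 4.25. The dopamine transporter gene SLC6A3 was listed at 0. DBH exceeded PNMT by 7.29 ± 0.29 on the log2 scale, SLC18A1 exceeded SLC18A2 by 4.69 ± 0.18, and CHGB lay below CHGA by a log2 difference of -2.58 ± 0.08, each in 3 of 3 libraries.

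Cholinergic genes gave 9 of 11 called above 1 FPKM and 2 below, with a median of 8.29 FPKM (percentile 64.5). The ganglionic nicotinic receptor subunit gene CHRNA3 stood at 73.8 ± 7.16 FPKM, CHRNA5 at 21.5 ± 2.43 and CHRNB2 at 20.7 ± 1.54, where CHRNA5 overlaps CHRNA3 on the other strand. The choline transporter gene SLC5A7 (0.00833 ± 0.00115 FPKM) and CHAT, the gene of acetylcholine synthesis (0.315 ± 0.219), were called below. The call for CHAT was lost without replicate 1 (limma adjusted p = 0.0670) and without replicate 3 (0.0788). TH exceeded CHAT by 1.67 ± 0.68 on the log2 scale in 3 of 3 libraries. The catecholamine list exceeded the cholinergic list by 1.83 ± 0.58 in 3 of 3 libraries, which did not pass the threshold (permutation p = 0.126, adjusted 0.149), and 5 cholinergic genes were called above at a level of 5 FPKM.

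Pan-neuronal genes were abundant, with 20 of 22 called above 1 FPKM and a median of 87.5 FPKM (percentile 100). STMN2, which encodes a microtubule regulator of growing axons, reached 2405 ± 71.9 FPKM, the ubiquitin hydrolase gene UCHL1 604 ± 28.8 and the neuronal tubulin gene TUBB3 308 ± 35.4. RBFOX3, which encodes the mature-neuron antigen NeuN, was called below at 0.241 ± 0.0497 FPKM, and the peripheral neurofilament gene PRPH (1.22 ± 0.389) was called neither. Schwann cell and glial genes lay at the other end, with 1 of 15 called above, 5 below and 5 listed at 0, PMP2 among them (median 0.084 FPKM, percentile 2.08). The member called above was the glial filament gene GFAP at 3.62 ± 1.895 FPKM, a call lost without replicate 2 (limma adjusted p = 0.0831). ERBB3 (1.704 ± 0.638 FPKM), S100B (1.17 ± 0.082) and ALDH1L1 (0.944 ± 0.514) were called neither. The neuronal list exceeded the glial list by a log2 difference of 8.90 ± 0.27 in 3 of 3 libraries (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted 0.00013).

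Proliferation genes were all called above 1 FPKM (25 of 25, median 64.4 FPKM, percentile 100). The replication helicase genes MCM4 (227 ± 31.7 FPKM) and MCM7 (208 ± 21.6) and the topoisomerase gene TOP2A (192 ± 17.5) were highest, and the G1/S cyclin gene CCNE2 (6.62 ± 1.58), which overlaps INTS8 on the other strand, was lowest. Cyclins D, CDKs and CDK inhibitors gave 11 of 14 called above and 1 below, with a median of 15.48 FPKM (percentile 91.6). CCND1 stood at 337 ± 34.3 FPKM, CDK4 at 226 ± 21.8, CDK2 at 71.5 ± 8.26 and CDK6 at 13.05 ± 0.889, while CCND2 was listed at 0 and CDKN2B was called below (0.192 ± 0.136). CDK4 exceeded CDK6 by 4.10 ± 0.24 on the log2 scale in 3 of 3 libraries, and no fold is given for CCND1 over CCND2. The proliferation list exceeded the cyclin and CDK list by a log2 difference of 2.04 ± 0.07 in 3 of 3 libraries (permutation p = 0.00153, adjusted 0.00284). The inhibitor gene CDKN1A had a value in replicate 1 only (42.4 FPKM) and was not tested.

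Of 10 anti-apoptotic genes 8 were called above 1 FPKM and 1 below (median 19.6 FPKM, percentile 93.9), and of 21 pro-apoptotic genes 17 were called above and 4 below (median 10.4 FPKM, percentile 82.7). The survival genes MCL1 (58.4 ± 1.83 FPKM), BIRC5 (55.8 ± 4.17) and BIRC2 (27.8 ± 0.676) were highest in the first list, with BIRC3 called below (0.0287 ± 0.0169) and BCL2A1 listed at 0. BAX, an effector of mitochondrial permeabilisation (189.6 ± 8.52 FPKM), CYCS (111 ± 9.05) and DIABLO (83.7 ± 1.52) led the second list, in which CASP8 (0.536 ± 0.101), BIK (0.216 ± 0.0828), CASP10 (0.158 ± 0.123) and HRK (0.047 ± 0.0347) were called below. BCL2 stood at 18.5 ± 2.06 FPKM, below BAX by a log2 difference of -3.35 ± 0.22 and below MCL1 by -1.66 ± 0.20, in 3 of 3 libraries. The lists differed by 0.90 ± 0.15 in 3 of 3 libraries, which did not pass the threshold (permutation p = 0.389, adjusted 0.389), and means over members gave -0.028.

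The signalling genes downstream of the receptor kinases were expressed without exception in the list, with 26 of 26 RAS-MAPK and PI3K-AKT genes called above 1 FPKM (median 31.3 FPKM, percentile 99.97). The adaptor gene SHC1 reached 335 ± 9.37 FPKM, the kinase gene MAP2K2 195 ± 11.4 and the phospholipase gene PLCG1 191 ± 10.2, and PIK3CD was lowest at 5.46 ± 1.14. The list exceeded the other receptor tyrosine kinases by a log2 difference of 2.08 ± 0.12 in 3 of 3 libraries (permutation p = 0.00019, adjusted 0.000412).

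Of the developmental pathways, BMP and TGF-beta genes gave 13 of 19 called above 1 FPKM and 4 below (median 9.99 FPKM, percentile 78.5), led by the signal transducers SMAD4 (65.4 ± 1.24 FPKM) and SMAD2 (58.9 ± 0.995) and by TGFB1 (56.7 ± 4.67), with the antagonist NOG and BMP4 listed at 0. The members below were BMP2 (0.479), TGFBR2 (0.363), TGFB3 (0.284) and TGFB2 (0.162). Wnt genes gave 14 of 21 above and 5 below (median 8.03 FPKM, percentile 69.8), led by the gene of beta-catenin, CTNNB1 (79.3 ± 4.62 FPKM), VANGL2 (49.8 ± 3.59) and GSK3B (42.7 ± 3.26), with WNT1 and LEF1 listed at 0. The Wnt receptor genes FZD4 (0.709) and FZD5 (0.604) and the ligand genes WNT11 (0.229), WNT5A (0.188) and WNT3A (0.0127) were below. Notch genes gave 12 of 16 above and 4 below (median 4.85 FPKM, percentile 48.1), led by DLK1, a non-canonical ligand (109 ± 17.5 FPKM), NUMB (47.7 ± 1.86) and RBPJ (37.3 ± 4.38). The Notch target genes HES1 (0.458 ± 0.0748) and HES5 (0.132 ± 0.0598) and the ligand genes DLL1 (0.0827 ± 0.0251) and DLL4 (0.055 ± 0.0391) were called below, and 7 Notch genes were called above at a level of 5 FPKM. Hedgehog genes gave 3 of 9 above and 4 below (percentile 15.52). The receptor genes PTCH1 (37.3 ± 9.24 FPKM) and SMO (21.8 ± 2.85) and the inhibitor gene SUFU (7.34 ± 0.124) were above, GLI2 (0.537), GLI1 (0.136) and HHIP (0.061) were among those below, and SHH was listed at 0.

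Guidance and chemokine genes of migrating neural crest cells gave 16 of 26 called above 1 FPKM and 5 below (median 7.05 FPKM, percentile 64.1). The adhesion gene NCAM1 stood at 124 ± 1.37 FPKM, the chemokine receptor gene CXCR4 at 90.1 ± 1.75 and the neural cadherin gene CDH2 at 48.3 ± 0.962. CXCL12, the ligand of CXCR4, and the ephrin receptor gene EPHA4 were listed at 0, so no fold is given for CXCR4 over CXCL12. Besides CDH1, the members below were SEMA3A (0.532), NRP1 (0.183), CDH7 (0.038) and CDH6 (0.004). CDH2 exceeded the epithelial cadherin gene CDH1 (0.412 ± 0.223 FPKM) by 6.65 ± 0.62 on the log2 scale in 3 of 3 libraries. CDH1 was called below 1 FPKM, but not without replicate 1 (limma adjusted p = 0.0756) or replicate 3 (0.0951).

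Angiogenic ligands gave 5 of 12 called above 1 FPKM and 3 below (median 0.797 FPKM, percentile 15.8), and endothelial receptors and angiogenesis regulators 4 of 13 above and 8 below (median 0.183 FPKM, percentile 6.25). VEGFB (104 ± 4.37 FPKM), VEGFA (41.9 ± 1.46), PGF (7.86 ± 0.42), FGF2 (3.61 ± 0.25) and ANGPT1 (1.65 ± 0.131) were the ligands above, 3 of which were called above at a level of 5 FPKM, ANGPT2 (0.59), PDGFA (0.182) and VEGFD (0.139) were below, FGF1 (1.004 ± 0.472) and HGF (0.34 ± 0.376) were called neither, and VEGFC and PDGFB were listed at 0. HIF1A (239 ± 12.6 FPKM), VHL (37.1 ± 1.201), EPAS1 (35.7 ± 8.47) and ARNT (26.99 ± 2.18), which belong to the oxygen-sensing pathway, were the members above in the second list. The endothelial receptor genes KDR (0.0303 ± 0.00924) and TEK (0.00567 ± 0.00981) were called below. VEGFA exceeded its receptor gene KDR by 8.33 ± 0.09 on the log2 scale and lay below VEGFB by a log2 difference of -1.31 ± 0.11, and HIF1A exceeded EPAS1 by 2.76 ± 0.29, each in 3 of 3 libraries. VEGFA overlaps a non-coding gene on the other strand, AL136131.3, at 156 ± 33.9 FPKM. The ligands exceeded the second list by 1.61 ± 0.42 in 3 of 3 libraries, which did not pass the threshold (permutation p = 0.387, adjusted 0.389).

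Hypoxia genes gave 11 of 12 called above 1 FPKM (median 40.4 FPKM, percentile 99.9), led by the glycolytic genes PGK1 (811 ± 73.2 FPKM) and LDHA (609 ± 82.7) and by BNIP3 (59.5 ± 2.44). PGK1 is also in the housekeeping list, and VEGFA, another member, is also among the angiogenic ligands. The carbonic anhydrase gene CA9 was called below at 0.35 ± 0.242, but not without replicate 1 (limma adjusted p = 0.0898) or replicate 3 (0.0766), nor with a pseudocount of 0.01 (0.0946). Heat shock and stress genes gave 15 of 17 above and 1 below (median 12.9 FPKM, percentile 87.2), led by the chaperone genes HSPA8 (817 ± 111 FPKM), HSP90AA1 (677 ± 64.1) and HSP90AB1 (669 ± 11.7). The immediate-early gene FOSB was called below at 0.175 ± 0.18, but not without replicate 2 (limma adjusted p = 0.0663) or replicate 3 (0.0588), and FOS (0.662 ± 0.33) was called neither. MHC class I genes gave 6 of 11 above and 5 below (median 2.12 FPKM, percentile 29.1). B2M, the invariant light chain gene, stood at 238 ± 19.3 FPKM and HLA-C at 19.1 ± 1.63, while PSMB8 (0.59), HLA-B (0.271), NLRC5 (0.245), TAP1 (0.0647) and the immunoproteasome gene PSMB9 (0.0217 ± 0.0193) were below. MHC class I genes and heat shock genes have close paralogs, so the split of reads between them is uncertain. B2M, a member of both the housekeeping and the MHC list, was left out of both. The housekeeping list then exceeded the MHC list by a log2 difference of 8.40 ± 0.37 in 3 of 3 libraries (permutation p = 0.00012, adjusted 0.000338).

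Markers of other cell types were low except for the fibroblast list. Immune markers gave 0 of 13 called above 1 FPKM by limma and 9 below (median 0.04 FPKM, percentile 1.23), with CD14 (0.48 ± 0.097 FPKM), CD74 (0.21 ± 0.153) and CD68 (0.138 ± 0.145) highest and ITGAM listed at 0. The call of CD68 below the level was lost without replicate 3 (limma adjusted p = 0.0530) and with a pseudocount of 0.01 (0.0668). Endothelial markers gave 0 of 9 above and 7 below (median 0.0147 FPKM, percentile 1.64), with CLDN5 (0.289 ± 0.114), ESAM (0.277 ± 0.103) and EMCN (0.034 ± 0.0489) highest and ERG listed at 0. Muscle and erythroid markers gave 0 of 12 above and 7 below (median 0.0107 FPKM, percentile 0.28), with MYH3 (0.533 ± 0.315), ALAS2 (0.071 ± 0.0376) and ACTA1 (0.0683 ± 0.0284) highest and HBB listed at 0. MYH3 was called neither, and was called below in TPM, where all values are lower (limma adjusted p = 0.0288). These 3 lists also had 0 members above at an unadjusted p under 0.05. Epithelial markers gave 1 of 10 above and 4 below (median 0.338 FPKM, percentile 9.58): the junction gene CLDN4 (1.55 ± 0.323) was above, MUC1 (2.75 ± 2.24) and EPCAM (1.61 ± 0.643) were called neither, KRT19 (0.473), CDH1, KRT18 (0.264) and KRT8 (0.184) were below, and KRT5 was listed at 0. The call of CLDN4 was lost in TPM, with no filter on low values and without replicate 2 or replicate 3.

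Fibroblast markers gave 6 of 10 called above 1 FPKM and 1 below (median 3.87 FPKM, percentile 43.5). The surface antigen gene THY1 stood at 60.1 ± 1.97 FPKM, PDGFRA at 40.2 ± 3.95 and PDGFRB at 29.8 ± 1.91, all 3 above, FAP was below (0.028) and POSTN was listed at 0. The collagen gene COL1A1 (3.79 ± 0.456) was called above, and COL1A2 (0.921 ± 0.475) and COL3A1 (0.919 ± 0.675) were called neither. Pan-neuronal genes exceeded the fibroblast markers by a log2 difference of 4.46 ± 0.12 (permutation p = 0.00252, adjusted 0.00410), the epithelial markers by 7.71 ± 0.25 (permutation p = 0.00013, adjusted 0.000338) and the immune markers by 9.38 ± 0.35 (permutation p = 2e-05, adjusted 0.00013), each in 3 of 3 libraries. Of the 13 list pairs, 9 passed the threshold, and in all 13 the list named first was higher in every library. The permutations are across genes, which are not independent replicates.

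**Figure D3:**
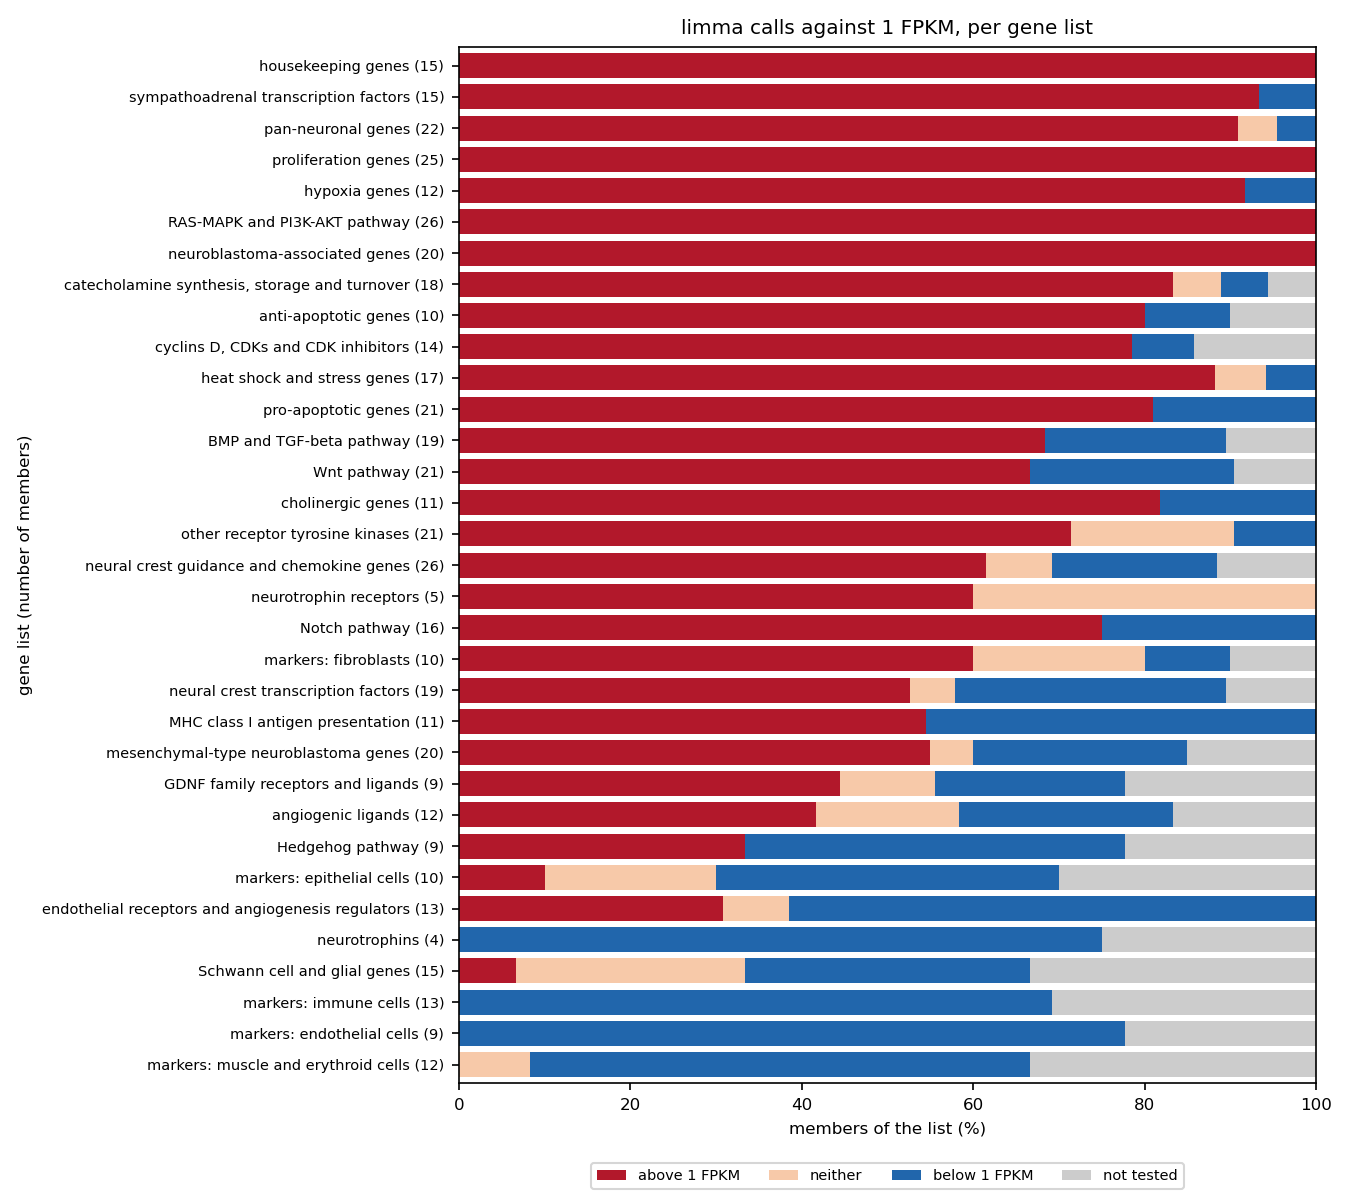
Share of the members of gene lists (%) called above 1 FPKM, below it, neither or not tested by limma over the 3 libraries, with the number of members in parentheses and lists ordered by their median level. All members were called above in 4 lists (housekeeping, proliferation, RAS-MAPK and PI3K-AKT, and neuroblastoma-associated genes), and 0 members in the neurotrophin, immune, endothelial, and muscle and erythroid lists.

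The counts adjusted over the list alone equalled those over all genes tested in each of the 34 lists. The median SD of log2(FPKM + 0.1) over 16090 genes of all types with a mean of at least 1 FPKM was 0.123. Pearson's r across the 12208 protein-coding genes among them was 0.988, 0.990 and 0.990 for replicates 1 and 2, 1 and 3, and 2 and 3. Across all 16090 genes r was 0.844, 0.845 and 0.850; genes are not independent replicates. No pair of libraries agreed within sampling noise (chi-square per gene of 6.10, 4.44 and 9.33 in recovered reads). The libraries thus differed by more than counting error, which argues against any of them being a plain copy of another. Reads shared in part between libraries were not excluded, since other reads could still differ. Nor does the comparison show that the flasks were separate. The count of 3 samples rests on the separate flasks named in the labels. Of 9004 genes with a mean of at least 10 FPKM, 347 differed more than 2 times between their highest and lowest library, of which 28 were protein-coding and 319 were not, or were not matched. The median exonic length of the 347 was 96 bases. Without replicate 1, 2 or 3 in turn, 220, 262 and 255 genes differed as much.

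Among genes with a mean of at least 10 FPKM, the 10 with the largest spread had a value above 0 in 1 or 2 libraries, and those with a match in the annotation had 58 to 70 exonic bases. RF02108 (58 exonic bases) stood at 1804, 0 and 894 FPKM in replicates 1, 2 and 3, SNORD48 at 348, 263 and 0, and the mitochondrial MT-TM at 0, 165 and 433. RNU7-71P (473 FPKM in replicate 2), RNU7-49P (458 in replicate 1), RNU7-75P (346 in replicate 2), the processed pseudogene AC084368.1 (307 in replicate 1) and MIR6777 (272 in replicate 1) had a value above 0 in a single library, and SNORD104 stood at 0, 404 and 177. The tenth was an identifier with no match in the annotation used. On the 66 exonic bases of MIR6777, 1 read was worth an estimated 272 FPKM in replicate 1. Its value there thus corresponds to about 1 read, if that estimate holds. On the 69 bases of MT-TS1, 1 read was worth an estimated 197, 149 and 97.6 FPKM in replicates 1, 2 and 3. The spread of genes this short can therefore rest on few reads. Among protein-coding genes, CEP97, a centrosomal gene chosen after its values were seen, was furthest apart, at 120, 11.8 and 97.8 FPKM.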

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

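All tests in this part were planned. The number of genes called above 1 FPKM ranged from 13720 to 14774 over the 11 alternatives that kept that level, against 14446; 15939 were called above 0.5 FPKM and 10429 above 5 FPKM. The number below moved from 13853 to 5918 at a mean FPKM of at least 0.1 and to 40037 with no filter, since fewer or more low genes were then tested. Of 1377 alternatives for single named genes, 1354 kept their side of the threshold, 16 lost it and 7 gained it; of 200 for gene pairs 199 kept their sign, and of 117 for list pairs 113 kept sign and side. Of 306 alternatives for list medians 96 moved by more than their spread over libraries, as did 34 of 68 percentiles by 5 points or more.

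At a level of 0.5 FPKM, 5 neurotrophin receptors, 4 glial and 3 epithelial genes were called above; at a level of 5 FPKM, 1 GDNF family, 5 mesenchymal-type, 5 cholinergic, 0 glial, 3 angiogenic ligand, 7 Notch and 0 epithelial genes, because the bar itself moved. With no test, 4 glial and 3 epithelial genes reached 1 FPKM in every library. In TPM 0 epithelial genes were called above, since that scaling lowers every value. With no filter 2 glial and 0 epithelial genes were; the cause was not tested. Leaving out each library gave 0 to 2 glial and 0 to 1 epithelial genes. Glial genes numbered 0 without replicate 2.

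The neurotrophin receptors exceeded the neurotrophins by 6.17 with a pseudocount of 0.01 and by 4.47 with means over members, and by 4.85 to 5.02 with a library left out; the pair passed the threshold in the first 2 settings and without replicate 2. Anti-apoptotic minus pro-apoptotic genes turned to -0.028 (adjusted permutation p = 0.981) with means; the cause was not tested. NTRK3 minus NTRK2 ranged from -0.22 to 0.12, positive without replicate 3. The median SD was 0.110 with a pseudocount of 1, 0.102 at a mean of at least 5 FPKM, and 0.0874 to 0.112 with a library left out. More than 1.5 times apart were 564 genes, and 220 to 262 were more than 2 times apart with a library left out. No paired analysis was possible because there is 1 group. Depth limits what can be said of genes under 0.139 FPKM per 3 reads on 1 kb in replicate 1.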

Other observations

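The gene groups of the first 2 paragraphs, and the tests of the mitochondrial tRNA genes and of the fibroblast markers, were chosen after the values were seen. Several genes that the fixed lists leave out were abundant. MDK, which encodes the growth factor midkine, stood at 901 ± 18.6 FPKM, and the G protein regulators RGS5 (3808 ± 160.3) and RGS4 (954 ± 36.6) ranked 4 and 32 among protein-coding genes other than ribosomal and mitochondrial ones. C7, which encodes a component of the complement attack complex, stood at 794 ± 110.4 FPKM (rank 40), while C3 (0.166 ± 0.143) was called below 1 FPKM by limma and C9 was listed at 0; of 12 complement genes 4 were called above and 7 below. The neuropeptide genes GAL (79.00 ± 9.18), NPY (63.7 ± 5.703) and VIP (14.5 ± 2.35) were called above, and PENK, TAC1, ADCYAP1 and CARTPT were listed at 0. Among retinoid genes, CRABP2 (89.1 ± 0.81) and CRABP1 (39.8 ± 7.202), which encode binding proteins, were among 8 of 11 called above, while the retinoic acid hydroxylase gene CYP26A1, an inducible target of retinoic acid, was called below at 0.012 ± 0.0208 FPKM.

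Of 9 genes whose surface or antigen products have been studied as neuroblastoma targets, 8 were called above 1 FPKM by limma, among them PRAME (201 ± 9.16 FPKM), GPC2 (97.5 ± 6.37) and CD276 (75.8 ± 8.45), and the somatostatin receptor gene SSTR2 (0.72 ± 0.0375) was called below. Of 5 genes of ganglioside GD2 synthesis 4 were above, with B4GALNT1 at 24.3 ± 2.12 FPKM, and the GD3 synthase gene ST8SIA1 (1.13 ± 0.208) was called neither. Of 11 growth factor and cytokine genes 6 were above, including GDF15 (45.3 ± 15.1). The HOX clusters, which pattern the body axis, differed: the 11 HOXA genes were listed at 0, 0 of 10 HOXB genes were called above, 3 of 9 HOXC genes were (HOXC4 18.03 ± 0.785, HOXC6 10.1 ± 1.44, HOXC9 3.29 ± 0.546), and so were 5 of 9 HOXD genes, led by HOXD8 (34.6 ± 1.61) and HOXD9 (17.8 ± 0.464). The only HOXB genes tested, HOXB7 and HOXB13, were called below, and the difference between the clusters was not tested.

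More genes had a value above 0 in replicate 3 (28813) than in replicate 1 (26486). Depth is a candidate explanation: among single-transcript genes 6202 had a read in replicate 3 and 5449 in replicate 1, 13.8% more, and after thinning replicate 3 to the depth of replicate 1 the number was 5387, a difference of -1.14%. The summed FPKM of the immune, endothelial, and muscle and erythroid markers in replicate 3 was 0.798 times that of replicate 1 (2.38 against 2.99). It thus gave no sign of more RNA of those cells in replicate 3. With list medians of 0.04, 0.0147 and 0.0107 FPKM, few reads lie behind this sum. Fibroblast, epithelial and glial markers were not part of it, so RNA of such cells was not addressed. With 1 group, no biological explanation was tested.

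MT-TC, MT-TS1, MT-TY and MT-TN held over 34% of summed FPKM in every library. A candidate explanation is the length term of FPKM, which inflates transcripts shorter than a fragment. The length term alone does not tell the 4 genes from other mitochondrial tRNA genes as short. MT-TE and MT-TI have 69 exonic bases, as MT-TS1 does, and had means of 10753 and 5589 FPKM. MT-TM, with 68, stood at 0, 165 and 433 FPKM in replicates 1, 2 and 3. On 66 exonic bases, 1 read was worth 272, 206 and 135 FPKM in replicates 1, 2 and 3, estimated from genes of that length. The 4 genes would then hold 0.0109%, 0.0128% and 0.0112% of the estimated reads in these libraries. The estimate rests on the lowest value above a fixed minimum at each length, from the library where it was smallest relative to depth. If that value stands for more than 1 read, these shares are too low. No biological explanation was tested.

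THY1, PDGFRA and PDGFRB, used here as fibroblast markers, were called above 1 FPKM. Fibroblasts in the cultures could bring these genes, but would also bring fibrillar collagens, and the median of COL1A1, COL1A2 and COL3A1 lay below that of the 3 markers by a log2 difference of -5.49 on average (-4.39, -6.25 and -5.84 in replicates 1, 2 and 3). Expression of the 3 genes by the tumour cells themselves may remain as a hypothesis, which was not tested. COL1A1 (3.79 ± 0.456 FPKM), DCN (14.7 ± 2.14) and LUM (3.95 ± 0.626), also fibroblast markers, were called above 1 FPKM, so a fibroblast share too low to bring the 3 genes was not excluded, and PDGFRA and PDGFRB are also in the list of receptor tyrosine kinases.

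In 28 genes a value was missing in 1 or 2 libraries, 14 in replicate 2 and 24 in replicate 3, and 27 of them lay in 11 loci. The largest held 8 genes, among them EIF4A2 (309 FPKM in replicate 1) and RFC4 (89.6), and CDKN1A (chromosome 6, 36676460 to 36687339) was missing in replicates 2 and 3. Among genes that did have values, the protein-coding LRRC14 stood at 52.2, 10.5 and 11.3 FPKM in replicates 1, 2 and 3.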
